A study of Rattus norvegicus with 16 samples.

How the data were processed

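Total RNA of whole embryonic kidneys from 2 inbred rat strains was measured on Affymetrix rat gene arrays, with biotin-labelled RNA, per the labels. Kidneys of the Munich Wistar Frömter rat (MWF), a strain with inherited albuminuria and few nephrons, were taken at E15.5. Kidneys of the spontaneously hypertensive rat (SHR) were taken at E16.0. Each strain had 4 samples of male kidney tissue, per the labels. The same 8 arrays were deposited at 2 levels of summary, 1 value per gene and 1 value per exon probe set, so the levels are not independent measurements. Strain and embryonic day cannot be separated in this design, and every difference below carries both. The labels do not say whether samples of a strain came from separate animals or litters, so p-values measure the spread between these samples.

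The deposited values were log2 intensities that the authors had summarised and normalized between arrays, as seen from their range and their nearly equal medians. Partek is the only tool named in the submitters' processing notes. Its version, the background correction, the summarisation method, the normalization method and any filter are not given in the sources used here. Gene-level array medians lay between 8.17 and 8.21, and exon-level medians between 7.93 and 7.99. Intensities have no read depth, so the number of arrays limits the precision. Detection calls were not analysed here, and a gene near the lowest intensities may have no measurable signal. No 2 arrays held identical values.

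There were 21371 probe sets at gene level and 213067 at exon level. Probe sets were named from the platform annotation, with symbols updated through a RefSeq gene table of assembly GRCr8. At gene level, 12936 probe sets had 1 gene symbol, 184 had several and 8251 had none, and 12915 of those with 1 symbol matched the RefSeq table. At exon level, 172924 probe sets had 1 symbol, 1661 had several and 38482 had none. Probe sets with several symbols or none were tested and counted but not named. The array build is not given in the sources used here, so no coordinates were used beyond chromosome and gene order in GRCr8. No genome sequence was used, and the probes were not searched for strain variants.

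Differences are MWF minus SHR on the log2 scale. Each table was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, strain as the only term, 4 arrays against 4). Calls were made at a Benjamini-Hochberg adjusted p under 0.05, and a second count required at least a 1.5-fold difference. Of the 27 gene lists fixed, 26 had measured members and were tested with limma's camera with a preset inter-gene correlation of 0.01, with 1 row per gene, the probe set with the highest mean over all arrays. Camera with an estimated correlation and fry were run beside it. Exon usage was tested with limma's diffSplice (Simes and F tests per gene) in genes with at least 3 probe sets. Shares of called genes per chromosome were compared by two-sided Fisher's exact tests, adjusted over 21 chromosomes. The samples, tests, gene lists, alternatives and naming rule were fixed before the data were examined.

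Genes are named by rule. The rule took the 12 largest differences in each direction among called probe sets with 1 symbol and no overlap between strains, leaving out provisional, olfactory and vomeronasal names. It also took up to 4 members with the smallest p in each list, the podocyte gene Tmem63c, and a list of genes with reported strain variants in SHR. For exon usage it took the 6 genes with the smallest Simes p. Th, Dbh, Chga, Chgb, Alb, Afp and Stmn2 were chosen after their values were seen, as were the list members named beyond the 4.

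The scripts were tested on simulated data with the real means and limma's moderated variances. Noise was drawn independently for each probe set, so shifts that many genes of an array share were not simulated. At gene level, 71% of changes of 0.5 on the log2 scale and 98% of changes of 1 were recovered among 21371 probe sets, with 15 false calls, 8.15% of the calls. At exon level, 1% of changes of 0.5 and 45% of changes of 1 were recovered among 213067 probe sets. In the exon usage test, 93.5% of changed genes were recovered, but 423 of 13664 unchanged genes were called as well. The false calls came with a variance shared by all probe sets of a gene, so a version with each probe set's own variance was added. It recovered 59% with 2 false genes.

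Alternatives covered the normalization, a filter on dim probe sets, the variance model, array weights, the replicate number as a block, each array left out in turn, and summaries of genes with several probe sets. After the data were seen, 4 more were added: leaving out SHR replicate 2 together with MWF replicate 1, covariates for sympathoadrenal and for liver genes, and the exon usage test with own variances.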

Results

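Embryonic kidneys of MWF rats (E15.5) and SHR rats (E16.0) were profiled on 8 arrays, 4 per strain. The comparison asked which genes differ between the kidneys of a strain that develops albuminuria and those of a hypertensive strain. Gene-level values correlated at 0.979 to 0.992 between arrays of a strain and at 0.971 to 0.986 between strains, across probe sets. The first principal component held 46.8% of the variance. The MWF arrays lay between -20.8 and -15.7 on it. SHR replicates 3 and 4 lay at 26.6 and 27.8 with SHR replicate 1 close to them, and SHR replicate 2 lay at -1.63, between the strains.

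The genes furthest above SHR in MWF kidneys were globins and other red cell genes, a class I histocompatibility gene and several genes outside the fixed lists. Hba-a3, an alpha globin, was 5.59-fold higher, with 10.35 ± 0.41 in MWF and 7.87 ± 0.23 in SHR (log2, SD, n = 4). RT1-N2, of the rat major histocompatibility complex, was higher by 2.28 ± 0.09 (SE) and Tmem163, a zinc transporter gene, by 2.08 ± 0.07. Rhd, Hbb-b1 and Hbg1, all expressed in red cells, were higher by 1.68, 1.63 and 1.18. Chchd2l3 was higher by 1.77, the receptor gene Gprc5c by 1.58, the desmosome and p53 target gene Perp by 1.58, the glutathione transferase gene Gstm6 by 1.33, Lipt1 by 1.32 and the DNA repair gene Aplf by 1.30. Gprc5c had 2 gene-level probe sets, of which the rule took the called one with the largest difference. Of its 6 exon-level probe sets 5 lay above 0, with a median difference of 0.46.

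In the other direction, Dlgap5l2 was 15.0-fold lower in MWF, at 4.76 ± 0.09 against 8.66 ± 0.19 in SHR (log2, SD, n = 4). The MWF value lay near the lowest intensities on the arrays. Dlgap5l2 had 3 gene-level probe sets, of which the rule took the called one with the largest difference. It had no named exon-level probe set. Ifit1, an interferon-induced gene, was lower by -2.54 ± 0.07 (SE), and Cyp2j4, an arachidonic acid epoxygenase gene, by -2.23 ± 0.08. Slc11a1, a metal transporter gene of macrophages, was lower by -2.17, Abcg3l3 by -1.99, Pop5, a subunit gene of RNase P and MRP, by -1.81, and the angiotensin-converting enzyme gene Ace by -1.70. RT1-CE16, the sodium channel gene Scn7a, the mediator subunit gene Med22, the phosphoribosyl pyrophosphate synthetase gene Prps1 and the melanocortin receptor gene Mc4r differed by -1.60, -1.58, -1.54, -1.53 and -1.51. For RT1-CE16 the median difference of its 9 exon-level probe sets was smaller, at -0.48. These 24 genes were named from called probe sets without overlap between strains, so passing the threshold followed from the rule. The largest limma adjusted p was 0.0316, for Ace.

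In all, 1407 of 21371 gene-level probe sets (6.58%) passed the threshold, 680 higher and 727 lower in MWF, and 441 of them differed at least 1.5-fold, 195 higher and 246 lower. Of the 1407, 910 had 1 gene symbol and stood for 892 distinct named genes, and 497 had none or several. An unadjusted p under 0.05 was reached by 4788 probe sets. The strains did not overlap in 14.4% of all probe sets, against 2.86% by chance. The count rose to 2279 without SHR replicate 2 (865 higher and 1414 lower, with 203 and 683 of 886 at least 1.5-fold apart), fell to between 775 and 905 without any 1 of MWF replicates 2, 3 and 4 or SHR replicates 1, 3 and 4, and was 971 without MWF replicate 1. It was 517 with the mean of 4 sympathoadrenal genes as a covariate, 752 with medians of exon-level probe sets, 872 without the probe sets dimmer than the median and 2397 with array weights (224 higher and 551 lower at least 1.5-fold apart).

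Among the renal lineages, most measured genes of the ureteric bud (15 of 19) and all of the distal nephron list (14) lay above 0, and 3 and 2 of them passed. In the ureteric bud and collecting duct list, 3 of 19 measured genes were higher, namely the RET-dependent transcription factor genes Etv4 (0.38 ± 0.08) and Etv5 (0.43 ± 0.09) and the collecting duct factor gene Tfcp2l1 (0.49 ± 0.11), and none was lower. Adjusted over the list alone, 4 were higher. The list shifted up as a set (camera adjusted p = 0.0081; adjusted p = 0.412 with an estimated correlation). The list of GDNF and RET signalling, which shares Etv4 and Etv5, had these 2 of 12 genes higher, also adjusted over the list alone (adjusted p = 0.0303; adjusted p = 0.583 with an estimated correlation). Ret itself, the receptor on ureteric bud tips, was at 0.35 ± 0.12 without passing (adjusted p = 0.124), and passed without SHR replicate 2 (0.45). The list means of SHR replicate 2, 8.48 for the ureteric bud and 9.43 for GDNF and RET signalling, lay among the MWF arrays (8.45 to 8.56 and 9.32 to 9.53), as did SHR replicate 1 for the latter (9.32). The calls of Etv4 and Etv5 were lost without any 1 array other than MWF replicate 1 and SHR replicate 2, that of Tfcp2l1 without any 1 array other than SHR replicate 2, and that of the GDNF and RET list without MWF replicate 3 or 4 or SHR replicate 3 or 4. With the sympathoadrenal covariate and with medians of exon-level probe sets neither list passed, at an adjusted p of 0.226 and 0.0539 for the ureteric bud.

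In the loop of Henle and distal tubule list all 14 measured genes lay above 0, and the tight junction gene Cldn10 (1.04 ± 0.09) and the membrane protein gene Mal (0.57 ± 0.14) passed. With adjustment over the list alone, 3 passed. The set test gave an adjusted p of 0.000417 (adjusted p = 0.332 with an estimated correlation). Without the probe sets dimmer than the median the set did not pass (adjusted p = 0.308), and Mal was lost without any 1 array other than MWF replicate 1 and SHR replicate 2. Nephron progenitor genes had 0 of 12 called by limma, also adjusted over the list alone, and the set did not shift (camera adjusted p = 0.261). Cited1 and Pax2 were at 0.33 ± 0.12 and 0.34 ± 0.12, and Osr1 at -0.42 ± 0.11. Cited1 passed without SHR replicate 2 (0.41) and Osr1 without MWF replicate 3. In the renal vesicle and early nephron list, the Wnt inhibitor gene Dkk1 was higher by 1.12 ± 0.12, while Sfrp2 (-0.35 ± 0.07) and the cadherin gene Cdh6 (-0.40 ± 0.09) were lower, of 19 measured. The same 1 higher and 2 lower passed adjusted over the list alone, and the set did not shift (adjusted p = 0.998). Sfrp2 was lost without MWF replicate 2 or SHR replicate 1, 3 or 4, and Cdh6 without these or MWF replicate 1.

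Of 19 podocyte genes, Plce1, a phospholipase gene mutated in inherited nephrotic syndrome, was higher by 0.63 ± 0.09. All 33 of its exon-level probe sets lay above 0. Its call was lost with the sympathoadrenal covariate and with medians of exon-level probe sets (highest limma adjusted p = 0.0732). Over this list alone, 2 were higher and 1 was lower, and the set's adjusted p was 0.0748. Rab3b was at -1.38 ± 0.41 without passing over all genes, and passed without SHR replicate 2 (-1.88). It was 5.79 in SHR replicate 2 and between 7.66 and 7.88 in the other SHR arrays. Tmem63c, a podocyte gene linked to albuminuria in MWF rats, differed by 0.14 ± 0.06 (adjusted p = 0.239), with 6.52 ± 0.10 in MWF and 6.38 ± 0.01 in SHR (SD, n = 4). Of its 22 exon-level probe sets 12 were higher and 10 lower. With their median per array it was at -0.24 (limma adjusted p = 0.125). Of 24 proximal tubule genes, Cdh16 (0.44 ± 0.09) and Pdzk1ip1 (0.34 ± 0.08) were higher, also adjusted over the list alone, and the set did not shift (adjusted p = 0.288). Pdzk1ip1 was lost without any 1 array other than SHR replicate 2, and Cdh16 without MWF replicate 2 or 3 or SHR replicate 1, 3 or 4. No glomerular basement membrane or laminin gene of 11 passed in either way of adjusting (set adjusted p = 0.212).

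In the lists of stroma, vessels, leukocytes and nerves most measured genes lay below 0, and few of them passed. Of 19 stromal genes, the proteoglycan gene Lum (-1.32 ± 0.31) and the Wnt inhibitor gene Sfrp1 (-0.38 ± 0.08) were lower; adjusted over the list alone, 3 were lower and 1 was higher (set adjusted p = 0.0244; adjusted p = 0.486 with an estimated correlation). Lum in SHR replicate 2 was 9.99, and the other SHR arrays lay between 11.11 and 11.23. Without SHR replicate 2, 9 stromal genes were lower. The set was lost with the sympathoadrenal covariate (adjusted p = 0.895), with medians of exon-level probe sets (adjusted p = 0.0611) and without MWF replicate 4 or SHR replicate 1, 3 or 4, Lum without any 1 array other than MWF replicate 1 and SHR replicate 2, and Sfrp1 without any 1 array other than MWF replicate 3 and SHR replicate 2. In the renin-angiotensin list 4 of 11 genes were lower, namely Ace, the angiotensin receptor genes Agtr1a (-0.78 ± 0.08) and Agtr2 (-0.63 ± 0.14), and the aminopeptidase gene Anpep (-0.51 ± 0.11). Adjusted over the list alone, 5 were lower and 1 was higher (set adjusted p = 0.0325; adjusted p = 0.332 with an estimated correlation). The calls of Ace and Agtr2 were lost without any 1 array other than SHR replicate 2. That of Anpep was lost without MWF replicate 3 or SHR replicate 1, 3 or 4. The call of the list was lost without MWF replicate 4 or SHR replicate 1, 3 or 4. It was also lost with the sympathoadrenal covariate (adjusted p = 0.197) and with medians of exon-level probe sets (adjusted p = 0.0609). Ace was 5.76 in SHR replicate 2, between 7.31 and 7.81 in the other SHR arrays and between 5.20 and 5.68 in MWF.

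Of 14 endothelial genes 13 lay below 0, led by Sox18 (-0.48 ± 0.13) and Esam (-0.39 ± 0.11), which did not pass (limma adjusted p = 0.0624 and 0.0716) except without SHR replicate 2 (Sox18 -0.58, Esam -0.48). With adjustment over the list alone, 3 were lower (set adjusted p = 0.0162; adjusted p = 0.583 with an estimated correlation). The list mean was 8.66 in SHR replicate 2, below all MWF arrays (8.68 to 8.77), and between 8.84 and 9.02 in the other SHR arrays. The set was lost without SHR replicate 3 or 4 and with medians of exon-level probe sets (adjusted p = 0.143), and its mean was 0.0098 with the sympathoadrenal covariate. Among 20 macrophage and leukocyte genes, Coro1a (-0.51 ± 0.07), Lcp1 (-0.66 ± 0.10) and Adgre1 (-0.94 ± 0.19), which encode 2 actin-binding proteins and the F4/80 antigen, were lower. Over this list alone, 15 were lower, and the set's adjusted p was 1.27e-06 (adjusted p = 0.412 with an estimated correlation). Without SHR replicate 2, 15 were also lower over all genes, and the list mean of SHR replicate 2 (7.36) lay among the MWF arrays (7.10 to 7.55). Adgre1 was lost without MWF replicate 2, 3 or 4 or SHR replicate 3 or 4, and the set with the sympathoadrenal covariate (adjusted p = 0.207).

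The list of neural crest, neurons and glia had the largest mean shift of all lists, at -1.20, but only the neuronal RNA-binding protein gene Elavl4 (-0.35 ± 0.06) passed of 16. Adjusted over the list alone, 11 were lower and 1 was higher (set adjusted p = 0.000107; adjusted p = 0.445 with an estimated correlation). The sympathoadrenal genes Th and Dbh, enzymes of catecholamine synthesis, and Chga and Chgb, proteins of secretory granules, varied within SHR. Their mean was 10.78, 10.99 and 11.16 in SHR replicates 1, 3 and 4, and 6.03 in SHR replicate 2. It was 8.14 in MWF replicate 1 and between 6.14 and 6.30 in the other MWF arrays. Th differed by -3.45 ± 1.13 between the strains (adjusted p = 0.107). Without SHR replicate 2, 13 genes of this list were lower in MWF, and with the mean of these 4 genes, themselves in the list, as a covariate the set did not pass (adjusted p = 0.519). The sympathoadrenal genes and a set of genes that separated all arrays by strain are drawn together in the plot of values per array.

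**Figure D1:**
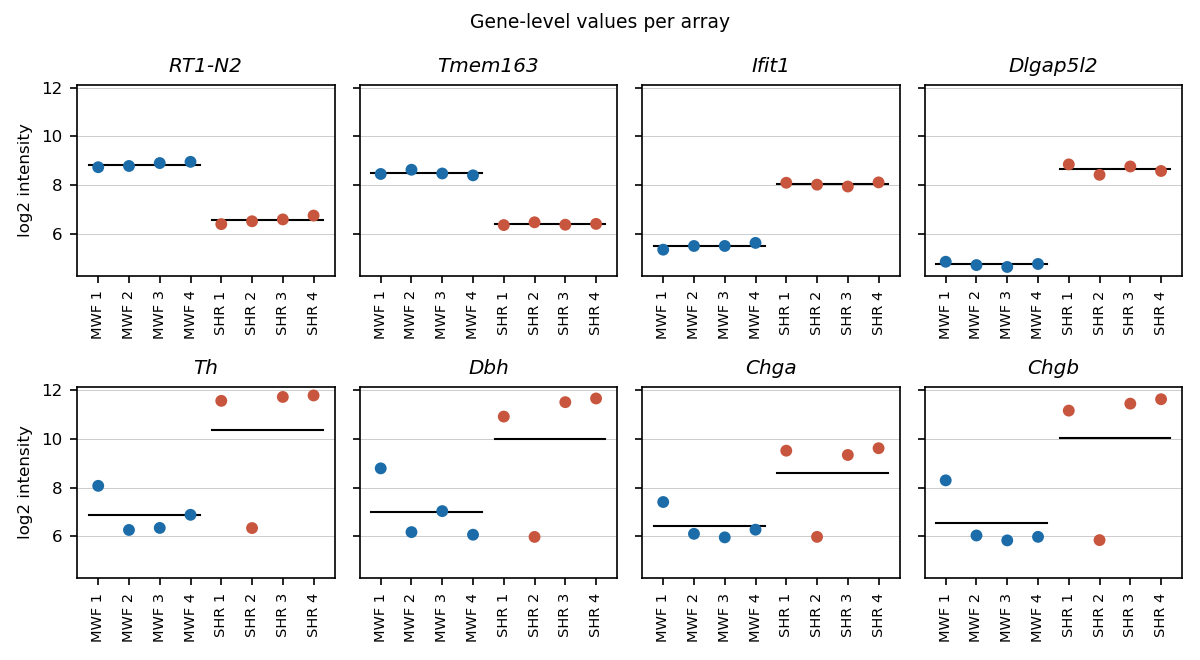
Gene-level log2 intensity of 8 genes on each of the 8 arrays (blue MWF, red SHR; black lines are strain means of 4 arrays). RT1-N2, Tmem163, Ifit1 and Dlgap5l2 were named from genes without overlap and so separated the strains on every array. In Th, Dbh, Chga and Chgb, SHR 2 lay at the level of the MWF arrays and MWF 1 lay above the other MWF arrays.

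All 16 measured members of the list of red cell genes lay above 0, with a mean shift of 0.86, and 5 passed, Rhd, Hbb-b1, Hbg1, Hbb (0.68 ± 0.15) and Hbe2 (0.52 ± 0.13). With adjustment over the list alone, 14 were higher (set adjusted p = 2.63e-08; adjusted p = 0.368 with an estimated correlation). Rhd was lost without MWF replicate 1 or SHR replicate 4, and Hbb without any 1 array other than MWF replicate 3 and SHR replicate 2. Liver genes were also present and differed between arrays of the same strain. Alb lay between 9.35 and 12.17 in MWF and between 8.63 and 12.12 in SHR. No liver gene of 14 passed in either way of adjusting, all lay above 0 with a mean of 0.60, and the set's adjusted p was 0.0748. The set passed without MWF replicate 3 (mean 1.03, adjusted p = 0.000639) and without SHR replicate 1 (1.06, adjusted p = 0.00026), as well as with array weights (adjusted p = 0.0402) and medians of exon-level probe sets (adjusted p = 0.0334), and its mean was 0.32 and 0.37 without MWF replicates 1 and 2 and 0.26 and 0.40 without SHR replicates 3 and 4.

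Hypoxia-response genes were lower as a set (adjusted p = 0.000352; adjusted p = 0.332 with an estimated correlation). Of 19 measured, 6 were lower and 1 was higher, and adjusted over the list alone 9 were lower and 1 was higher. The lower genes were Adm (-0.87 ± 0.17), a vasodilator peptide gene, the metabolic genes Pdk1 (-0.42 ± 0.08), Aldoc (-0.68 ± 0.15) and Ldha (-0.29 ± 0.07), the collagen hydroxylase gene P4ha1 (-0.56 ± 0.10) and the oxygen sensor gene Egln3 (-0.51 ± 0.13). Ankrd37 was higher by 0.79 ± 0.11 at gene level, but of its 5 exon-level probe sets 3 were higher and 2 lower, with a median of 0.02. Its call was lost with medians of exon-level probe sets (limma adjusted p = 0.269). Adm was lost without MWF replicate 3 or SHR replicate 4, and Pdk1 without MWF replicate 4 or SHR replicate 4. With the sympathoadrenal covariate the calls of Adm, Pdk1 and P4ha1 were lost, while the set still passed. Adm was 6.60 in SHR replicate 2 and between 7.34 and 7.37 in the other SHR arrays.

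Of 25 cell cycle genes 20 lay above 0, with a mean of 0.08, and 2 passed. Mcm2 (0.29 ± 0.06), a DNA replication gene, and the mitotic cyclin gene Ccnb1 (0.37 ± 0.09) passed, also adjusted over the list alone (set adjusted p = 0.0325; adjusted p = 0.713 with an estimated correlation). The list mean was 10.99 in SHR replicate 2, above the MWF mean of 10.94, and between 10.80 and 10.82 in the other SHR arrays. The set was lost without MWF replicate 4 or SHR replicate 1, 3 or 4 and with the liver covariate, and its mean was -0.020 with the sympathoadrenal covariate (adjusted p = 0.895). The calls lost among its genes were Ccnb1 without any 1 array other than SHR replicate 2, and Mcm2 without any 1 array other than MWF replicate 1 and SHR replicate 2.

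Other lists held genes that moved apart without a shift of the set. Of 34 measured genes of antigen presentation, RT1-N2, RT1-N3 (0.64 ± 0.08) and RT1-M6-1 (0.48 ± 0.11) were higher, and RT1-CE16, RT1-DMb (-0.94 ± 0.09) and RT1-CE10 (-0.62 ± 0.08) were lower. Over this list alone, 4 were higher and 3 lower (set adjusted p = 0.998). Class I genes of this complex are near-identical copies, so their probe sets may not be specific. Of 26 genes of glutathione and xenobiotic metabolism, Gstm7 (0.61 ± 0.08), Gstm1 (0.51 ± 0.09), Gclm (0.44 ± 0.11) and Gstm3 (0.36 ± 0.09) were higher and Gstt2 (-0.49 ± 0.06) was lower. Adjusted over the list alone, 6 were higher and 3 lower (set adjusted p = 0.247). Gstm3 was lost without any 1 array other than SHR replicate 1. With medians of exon-level probe sets it was at -0.016 (limma adjusted p = 0.971), though 5 of its 7 exon-level probe sets lay above 0. Of 45 oxidative phosphorylation genes, Ndufb2 was higher by 0.73 ± 0.08, also adjusted over the list alone (set adjusted p = 0.707). Of 12 p53 target and cell death genes, Perp was higher and Ei24 lower (-0.32 ± 0.06), also adjusted over the list alone (set adjusted p = 0.939).

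Of the 10 measured genes with reported strain variants in SHR, Endog, a mitochondrial nuclease gene, was higher in MWF by 0.84 ± 0.08, the fatty acid transporter gene Cd36 by 0.80 ± 0.20 and Gstm1 by the value above. The same 3 passed adjusted over the list alone (set adjusted p = 0.0748). Acsm3, Ephx2, Folr1, Kcnj10, Ogn, Zbtb16 and Agtr1b did not pass, at values from -0.54 (Ogn) to 0.28 (Agtr1b), except that Ogn passed without SHR replicate 2 (-0.81). The adrenal cortex (8 measured, adjusted p = 0.0748), gonad and mesonephros (15, adjusted p = 0.587), skeletal muscle (11, adjusted p = 0.309) and immediate early gene lists (12, adjusted p = 0.0889) had 0 called genes in either way of adjusting. The muscle set passed without MWF replicate 3 (adjusted p = 0.0348). In at least 1 fit without 1 array, the gonad list genes Lhx9, Gata4 and Cyp26b1 and the immediate early gene Fos passed. Their lowest limma adjusted p values were 0.0158, 0.0197, 0.0186 and 0.0454.

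In total 11 of 26 lists passed, 5 higher and 6 lower in MWF, and 0 of these passed with the estimated correlation. The count was 7 without MWF replicate 4 and 6 without either of SHR replicates 3 and 4. By limma's fry, which tests a list without comparing it with other genes, 8 lists passed. The adjusted p was 0.00682 for the loop of Henle and SHR variant lists, 0.0163 for the podocyte, renin-angiotensin and adrenal cortex lists, 0.0204 for the hypoxia and immediate early gene lists and 0.0384 for the erythroid list. Median, mean and set test differed in sign in 4 lists that did not shift. The p53 list had a median of -0.02 and a mean of 0.09 with the test lower, the gonad list 0.10 and -0.01 with the test higher, the antigen presentation list -0.01 and 0.01 with the test lower, and the renal vesicle list -0.01 and 0.03 with the test higher.

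**Figure D2:**
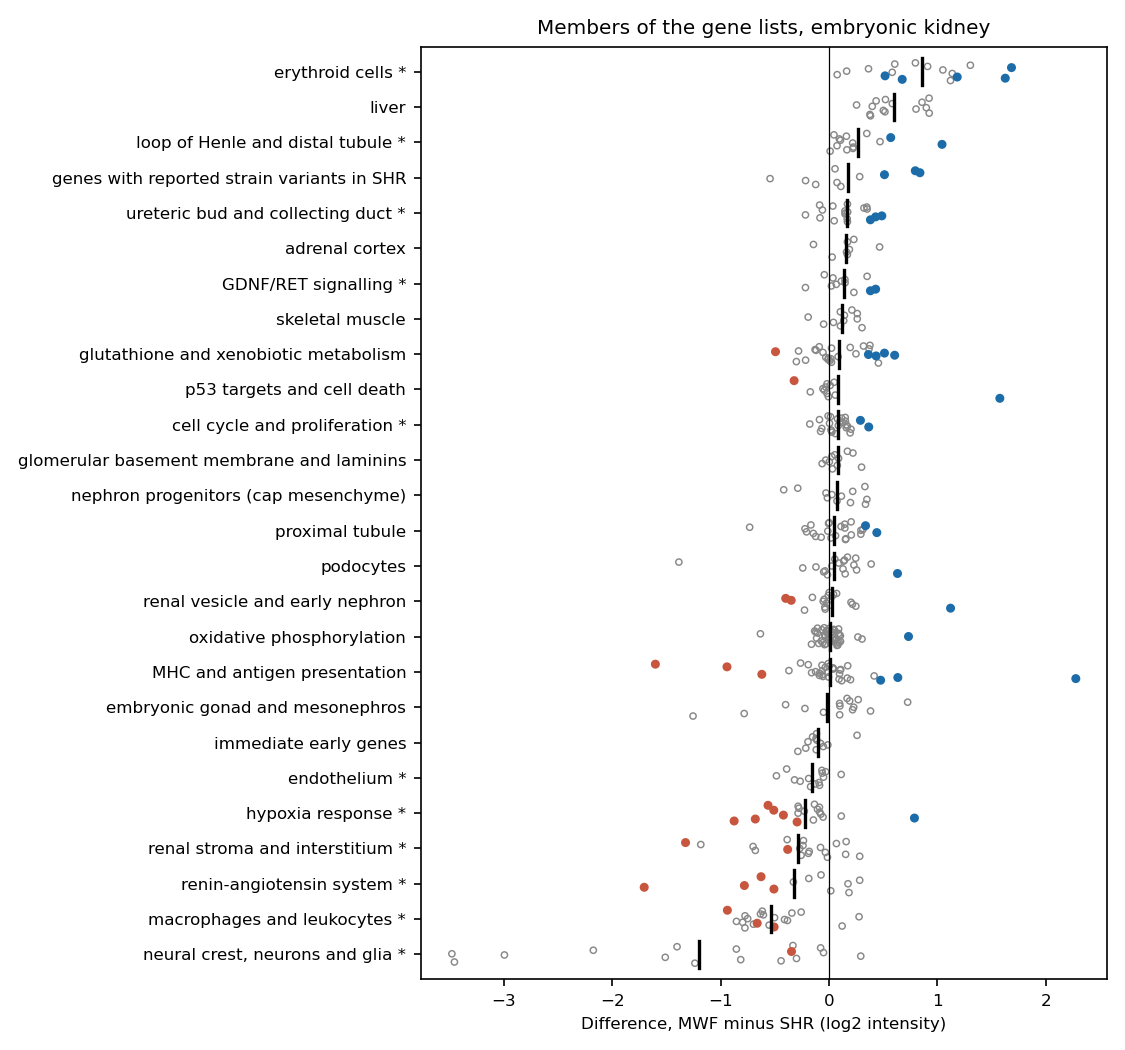
Difference between MWF and SHR (log2 intensity, x axis) of each measured member of the 26 gene lists (y axis), with a black bar at the list mean. Filled points passed the adjusted threshold over all genes (blue higher, red lower in MWF), open points did not, and a star marks the 11 lists called by camera with its preset correlation. The neural crest, neurons and glia list had the lowest mean, -1.20, and the erythroid list the highest, 0.86.

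At exon level, 4112 of 213067 probe sets (1.93%) passed, 1901 higher and 2211 lower in MWF, and 3544 of them differed at least 1.5-fold. An unadjusted p under 0.05 was reached by 29264. With 1 gene-level probe set per gene, the one with the highest mean, 877 named genes were called, of which 780 had at least 3 exon-level probe sets. In 750 of these the median probe set moved in the gene-level direction, and 424 passed with the median of the probe sets. Across 11058 genes, which are not independent replicates, the differences at both levels correlated at 0.867. All 12 exon-level probe sets of Cyp2j4, all 9 of Tmem163 and all 3 of Ifit1 moved with the gene-level value. The exon-level count was 6210 without SHR replicate 2, 1975 higher and 4235 lower. It was 2446, 2432, 2496, 2494 and 2405 without MWF replicates 2, 3 and 4 and SHR replicates 3 and 4, and 1382 with the sympathoadrenal covariate.

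Within single genes, a few probe sets differed far more than the rest. In Pbrm1, a chromatin remodelling gene, 1 probe set of 33 was higher in MWF by 5.73 ± 0.12, at 9.96 ± 0.07 against 4.23 ± 0.24 in SHR (log2, SD, n = 4), while the median of the others was 0.00. The same pattern of 1 leading probe set was found in Dip2a (5.73 ± 0.09 of 86 probe sets) and the unconventional myosin gene Myo10 (4.94 ± 0.12 of 39). It was also found in the centriole gene C2cd3 (4.94 ± 0.15 of 34) and the adaptor complex gene Ap3d1 (4.10 ± 0.16 of 31). The extracellular matrix gene Hmcn1 had several such probe sets, led by 1 at 4.79 ± 0.21 of 109. The medians of the other probe sets of these genes lay between -0.08 (Ap3d1) and 0.26 (Hmcn1). All 6 had the low value in SHR. Further probe sets reached 4.52, 2.93 and 2.44 in Hmcn1, 1.89 in C2cd3, 1.68 in Dip2a and -1.48 in Myo10.

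Exon usage differed in 2106 of 13864 genes by the Simes test and in 1653 by the F test. With each probe set's own variance the count was 1143, of which 1029 were also among the 2106. In simulated data the first test called 423 unchanged genes, so its count is an upper figure. Of 2974 called probe sets, 1282 were lower in MWF than the rest of the gene, and 1423 of 2004 genes had exactly 1. A sequence difference between strains under a probe gives the same signal as a difference in exon use, and the probes were not checked for it. The same limit applies to gene-level calls. Of 1694 exon usage genes with a gene-level value, 365 were also called at gene level, where 119 would be expected from unrelated calls. The cause of this excess was not tested.

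The probe sets of Cd36 moved in opposite directions. The gene-level value was higher in MWF by 0.80 ± 0.20. At exon level 1 probe set was higher in MWF by 2.25 ± 0.41, and 2 were lower by -3.03 ± 0.28 and -5.03 ± 0.17. The last stood at 4.55 ± 0.09 in MWF and 9.58 ± 0.35 in SHR (log2, SD, n = 4). With the median of its 7 probe sets per array, Cd36 was lower in MWF by -1.02 (limma adjusted p = 0.0328). The probe sets with identifiers directly after the gene-level one lay between -0.02 and 2.25, and the 2 lower ones came after a gap in the identifiers. Whether the gene-level value was summarised from these as well was not checked, so it and the median may not rest on the same probes. The gene-level call was lost without any 1 array other than MWF replicate 3.

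**Figure D3:**
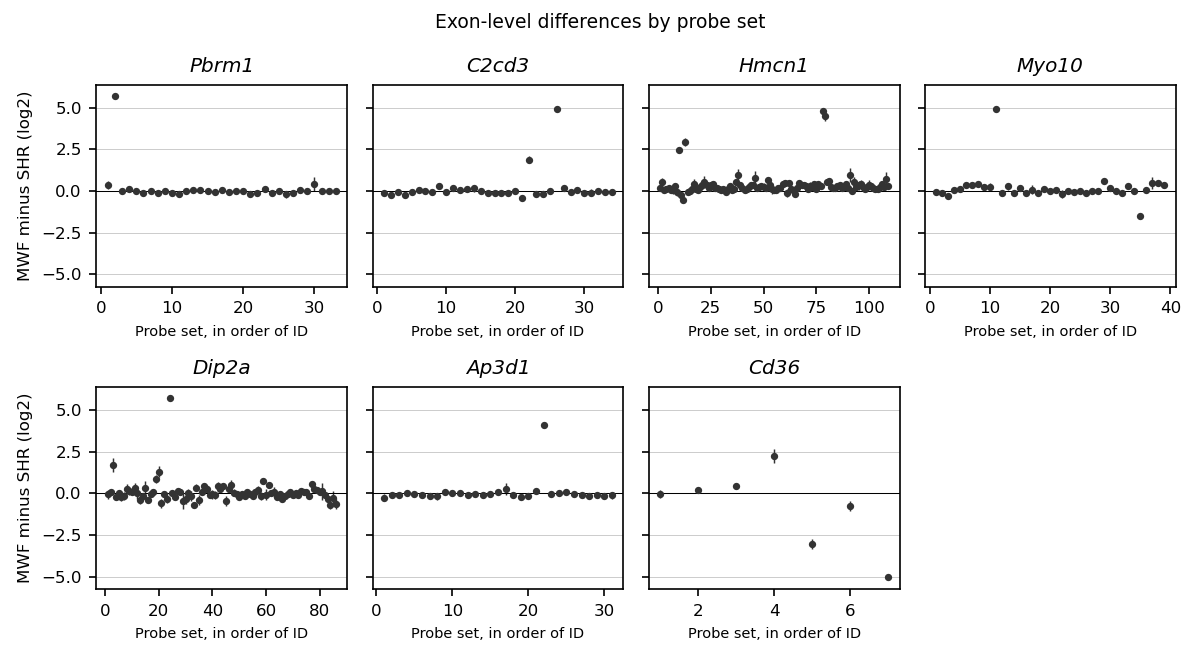
Exon-level difference between MWF and SHR (log2 intensity, y axis, bars are standard errors from limma) for each probe set in order of its identifier (x axis) in the 6 named genes and Cd36. The leading probe set differed by 4.10 to 5.73 in the 6 genes, with a second at 4.52 in Hmcn1, and Cd36 held probe sets from -5.03 to 2.25.

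The genes called at gene level were spread over all chromosomes of assembly GRCr8. Chromosome 6, named in advance because an albuminuria locus of MWF lies on it, had 33 of 492 genes called (6.71%), against 7.20% elsewhere (two-sided Fisher's exact test, p = 0.789, adjusted p = 0.920). Chromosome 4 had 75 of 748 genes called against 6.99% elsewhere (adjusted p = 0.0422), and chromosome 10 had 5.02% against 7.38% (adjusted p = 0.0422). With 1 array left out, 1 chromosome passed without MWF replicate 1, MWF replicate 4 or SHR replicate 4, and 0 passed without any of the other 5 arrays.

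None of the 9 sex marker genes had a named gene-level probe set, so the gene-level check was not made. At exon level the Y-linked gene Uty had 28 probe sets, whose median per array lay between 10.32 and 10.68 over the 8 arrays.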

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

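The test on further sympathoadrenal genes was set before their values were seen, and every other test in this part was chosen after the result was seen. The sign in which that first test was written was turned round after it had been run, with its bounds unchanged. The test of a shared strain or day difference was first made on Th, Dbh, Chga and Chgb (-0.16) and later, with their values seen, on the 18 further genes. The test of a mixture of the 2 strains was rewritten 2 times after its values had been seen, and its outcome depended on its form. Over all 2279 genes called without SHR replicate 2, 34.4% had SHR 2 at under 0.25 of the way from the MWF mean to the other SHR arrays and 35.4% at over 0.75, which spoke against a mixture. Among the 317 genes at least 2-fold higher in SHR these shares were 73.8% and 14.2%, which spoke for a mixture under the bound then used. The form kept uses genes higher in MWF, since a mixture that places most genes higher in SHR near MWF would hold mostly MWF RNA and would place genes higher in MWF there as well.

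A sample was singled out where its gap to the nearest array of its strain exceeded the 95% limit of Dixon's test, as a share of the range of the 4 arrays. Of 316 groups 29 exceeded the limit, where chance gives about 1 in 20 groups, and 17 of the 29 concerned SHR 2. SHR 2 was the lowest SHR array in Slc11a1 (0.849), Mc4r (0.873), Rab3b (0.894), Lum (0.901), Elavl4 (0.871), Adm (0.963), Gstt2 (0.846), Ogn (0.838), Th (0.959), Stmn2 (0.884), Dbh (0.869), Chgb (0.919) and Chga (0.924). It was the lowest in the means of the stromal list (0.844) and of the neural crest, neuron and glia list (0.864), and the highest in those of the cell cycle list (0.935) and the p53 list (0.834). Th, Stmn2, Dbh, Chgb and Chga had been chosen after their values were seen.

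MWF 1 was the lowest MWF array in Pop5 (0.867), Cldn10 (0.939) and Ei24 (0.882) and the highest in Chgb (0.919). MWF 3 was the highest in Plce1 (0.861) and the lowest in Agtr2 (0.832) and in the proximal tubule list (0.918). MWF 4 was the lowest in Dab2 (0.865) and the highest in Cyp11a1 (0.859) and in the cell cycle list (0.846). SHR 1 was the lowest SHR array in RT1-CE16 (0.834), and SHR 3 was the highest in Ndufb2 (0.845).

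Sympathoadrenal genes were low in SHR 2 and high in the other SHR arrays. SHR 2 lay at -0.051 of the way from the MWF mean (0) to the other SHR arrays (1) in the mean of the 18 further sympathoadrenal genes. This restates that SHR 2 was low, and shows only that the excess was not shared by all SHR arrays. It cannot tell whether a strain or embryonic-day difference contributed to the high values of the other SHR arrays, so that stays open. A whole adrenal gland is argued against, since the 8 cortex genes had a median of -0.048 in SHR 2 minus the other SHR arrays. A candidate explanation is sympathetic or chromaffin tissue on the other SHR kidneys: 18 of 20 further marker genes, none in another list, had a median of -1.42, between -0.08 and 0.70 for the other 7 arrays taken in the same way. Of the 18, 16 lay below all other SHR arrays, but the abundant Uchl1 (10.36) and Npy (8.45) did not, and an embryo age or innervation particular to SHR 2 stays open, as untested.

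SHR 2 lay between the strains on the first principal component, nearer the MWF arrays. Across all gene-level probe sets it correlated with the MWF arrays at a mean of 0.983 and with the other SHR arrays at 0.980. Every other array correlated better with its own strain. A mislabelled MWF kidney is argued against, since 35.4% of the genes called without it had SHR 2 at over 0.75 of the way to the other SHR arrays, among them Ifit1 (0.99), RT1-N2 (1.03) and Tmem163 (0.96). A mixture of the strains is argued against in the form kept, since 70% of the 50 genes at least 2-fold higher in MWF did so, where the other arrays gave between 69.8% and 90.2%. Tissue on the other SHR kidneys that SHR 2 lacks may explain the pattern: SHR 2 lay at under 0.25 for 45.3% of 1414 genes higher in SHR and 16.6% of 865 higher in MWF, a ratio of 2.72. What placed 144 genes of the latter group near MWF stays open.

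All 16 erythroid genes lay above 0 in MWF minus SHR. The list's mean difference was 0.86 without and 0.68 with the liver score as a covariate, and 7 of its genes passed by limma with it. With this covariate the set passed at the preset correlation (camera adjusted p = 2.22e-10) but not at an estimated correlation (adjusted p = 0.344). Liver tissue as the whole cause is therefore argued against only under the preset correlation. More red blood cells in the MWF samples stay open, since the 11 genes other than globins (median 0.91) belong to the list that showed the pattern and cannot test it. A difference in residual blood from dissection and a difference in embryonic blood between strains or days were not tested apart from each other.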

How the results depend on the processing

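The covariates, the fit without SHR replicate 2 and MWF replicate 1 together and the exon usage test with own variances were chosen after the data were seen. Of 61 named called genes, 30 passed under every alternative tried for them, and 22 of the 24 named by size passed in all 8 fits without 1 array, the exceptions being Ace and Rhd. Quantile normalization (1411 probe sets) and centring on medians (1408) left the 6 counts within 1.5 times.

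Leaving out 1 array gave 775 to 2279 gene-level probe sets, 363 to 886 at least 1.5-fold apart, 6 to 12 lists, 0 to 1 chromosomes, 2405 to 6210 exon-level probe sets and 1744 to 2233 genes with exon usage; fewer samples lower the power. The highest counts came without SHR replicate 2, except for the lists (12 without MWF replicate 3, 11 without SHR replicate 2) and the chromosomes. Without SHR replicate 2 and MWF replicate 1 the values were 2180 probe sets, 916 at least 1.5-fold apart and 0 chromosomes. With the probe sets dimmer than the median left out they were 872, 160, 1 chromosome and 1261 genes with exon usage, with fewer tested, and with the dimmest 0.25 left out 0 chromosomes. With array weights they were 2397, 775 and 1 chromosome, with trend and robust 4 chromosomes, and with genes at least 1.5-fold apart alone 1 chromosome. Medians of exon-level probe sets gave 752 and 7 lists, and own variances 1143 genes with exon usage. Except where fewer samples or probe sets were used, the cause was not tested.

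With the sympathoadrenal covariate the counts were 517, 3 lists, 0 chromosomes and 1382 at exon level. This covariate runs largely along strain, so part of the loss follows from its construction. With replicate number as a block they were 1312 (1014 shared), 9 lists (liver gained, and GDNF and RET, renin-angiotensin and cell cycle no longer past the threshold), 1 chromosome and 2172 at exon level; the samples were not taken as pairs, since no label ties the numbers and 1 of the same-number correlations (0.28, 0.15, 0.098 and 0.16) was under 0.1. As a hint from the data, MWF 1, 2 and 3 and SHR 1 and 4 correlated best with their own number, and MWF 4 and SHR 2 and 3 did not.

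Directions reversed as follows, and the cause was not tested: antigen presentation -0.0077 (quantile normalization), proximal tubule -0.024 (dimmest 0.25 of probe sets left out); with the sympathoadrenal covariate nephron progenitors -0.042, renal vesicle -0.021, endothelium 0.0098, gonad 0.11, muscle -0.091, cell cycle -0.020, oxidative phosphorylation -0.064, Mdm2 -0.0051, Acsm3 -0.054, Ogn 0.087 and Zbtb16 -0.035; with exon-level medians Kif11 -0.010, Gstm3 -0.016, Cd36 -1.02, Kcnj10 -0.011 and Tmem63c -0.24. Without 1 array, or without SHR replicate 2 and MWF replicate 1, the gonad list ranged from -0.10 to 0.046, antigen presentation from -0.034 to 0.035, oxidative phosphorylation from -0.0068 to 0.063, Zbtb16 from -0.0032 to 0.13 and Kcnj10 from -0.0069 to 0.11. Trend and robust was not run for lists and exon usage. List members named beyond the 4 were not recomputed. Genes that make up a covariate were not tested under it, nor was the liver list under the liver covariate. The neural crest, neuron and glia list, which holds the genes of the sympathoadrenal covariate, was tested under that covariate. Signal over background limits genes near the lowest intensities, where a difference can be compressed.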

Other observations

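The tests on further interferon genes, on neighbouring genes and on the splits of the arrays were set before their values were seen, and the genes named here were chosen after.

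Without SHR 2, the vesicular monoamine transporter genes Slc18a2 and Slc18a1 were lower in MWF by -3.30 and -3.21, and the G-protein regulator gene Rgs4 by -3.00. The neuropeptide gene Npy lay between 8.29 and 8.65 in SHR and between 8.35 and 8.74 in MWF. SHR 2 lay at -0.05 of the way from the MWF mean to the other SHR arrays in Slc18a2, at -0.05 in Slc18a1 and at 0.92 in Dlgap5l2.

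Ifit1, low in MWF, raised the hypothesis that interferon-stimulated genes may be lower as a group. Of 24 further genes, 17 were measured, 4 were lower (Oas1a -0.93, Ifih1 -0.86, Oasl -0.43 and Stat2 -0.36) and Ifi44l was higher by 0.93. The group as a whole did not pass (camera, unadjusted p = 0.0979, and 0.291 with an estimated correlation).

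Strain-specific haplotypes might place called genes side by side. There were 65 pairs of neighbouring called genes in the order of GRCr8, with pairs of similar name left out. Shuffles within chromosomes gave a mean of 60.2, with 75 at the upper end of their middle 95% (permutation p = 0.274), so an excess was not shown.

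The 8 arrays can be split into 4 and 4 in 35 ways. Only 1 of the 35 splits, the real one, gave as many gene-level probe sets (1407, highest other 232). The smallest p that such a permutation can reach is 0.0286, so chance is made unlikely but not excluded. The real split also had the highest count at least 1.5-fold apart (441, highest other 161) and at exon level (4112, highest other 42). The same held for exon usage (2106, highest other 930). These counts come from the same 8 arrays and are not separate support. The splits say nothing about the chromosomes (1 split; 2, highest other 0), since 33 of the 34 other splits had 0 gene-level probe sets past the threshold and so no genes to place. For the gene list shifts the real split did not stand out, and chance stays open. At least as many lists were given by 4 of the 35 splits (11, highest other 13). The split with 232 probe sets and 13 lists set MWF 1 and SHR 1, 3 and 4, the 4 arrays with the highest sympathoadrenal mean, against the others.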
